A study of Homo sapiens with 6 samples.

How the data were processed

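The series measured circular RNAs (circRNAs), which are closed RNA molecules made when the end of an exon is joined back to an upstream start, in cultured Ishikawa cells, a human endometrial carcinoma cell line. Per the labels, 3 libraries came from cells treated with MPA and 3 from untreated control cells. The labels gave no dose, no duration and no account of the cell culture, and they did not spell out MPA.

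The table deposited by the authors lists counts of back-splice junction reads per circRNA and library, per the file headers, with no normalization. The submitters' processing notes name CASAVA 1.8, BWA and the genome build hg19, without saying what each was used for; the circRNA caller is not given in the sources used here. Coordinates are therefore given on hg19 as the table gives them, with the start counted from 1. Host gene names, the 5 circRNA classes (exonic, sense overlapping, intronic, intergenic and antisense), circBase identifiers and predicted lengths in bases (another deposited column) are the authors' annotation. How each class was defined is not given in the sources used here. Every listed circRNA had at least 2 junction reads in at least 1 library. Log-scale CPM values of the same libraries in 6 further columns were not used.

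Library totals of junction reads ran from 3740 to 5454. These are reads across back-splice junctions only; the total sequencing depth of each library is not given in the sources used here, so a change in all circRNAs together was not separable from a change in depth. At a total of 3740 reads, a count of 0 allowed a share of up to 0.0802% (3 counts). Read-ratio intervals are exact binomial intervals at the 95% level and, like this limit, cover counting error only. The libraries were compared with each other by chi-square tests over the tested circRNAs and the pooled rest. The statistic per degree of freedom ran from 1.24 to 1.82, and every pair within a group differed by more than sampling noise (largest chi-square p = 0.00581), so no library of a group was a copy of another. This does not show separate cultures, since library preparation alone can exceed sampling noise. The least different pairs lay between groups: control 3 with MPA 3 (1.24, chi-square p = 0.0602) and control 2 with MPA 1 (1.25, chi-square p = 0.0558). Each library was counted as 1 replicate, per the labels.

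circRNAs with a mean of at least 5 reads over the 6 libraries were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling on the circRNA totals, a group term, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at an FDR of 0.05. Standard errors and 95% intervals of log2 fold changes were computed back from the quasi-likelihood p. Reads were also summed per host gene and tested in the same way; 10 circRNAs without a host gene name (0.0806% of reads) stayed out of these sums. Host gene lists were compared with camera (limma 3.58.1, preset correlation 0.01, with an estimated correlation beside it). For detected circRNAs, the number expected after thinning each library to the smallest total was also computed. Library totals, detected circRNAs and read shares were compared by two-sided exact permutation tests, whose smallest p with 3 libraries against 3 was 0.1. DESeq2 1.42.0 served as the other count test. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.

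The groups, the filter, the tests, 9 host gene lists and the rule for naming circRNAs were fixed before the data were examined. The rule took the 10 circRNAs with the smallest p in each direction among those past the threshold, or the 5 with the smallest p where none passed, the 5 with the highest mean, up to 3 per list, a set fixed by circBase identifier, and the 5 host genes with the smallest p. The lists were progestin and decidual response, cell cycle and DNA replication, chromatin and transcription regulators, RNA processing and splicing, PI3K, AKT and mTOR signalling, TGF-beta, SMAD and Wnt signalling, adhesion and cytoskeleton, ubiquitin and protein turnover, and markers of other cell types. Gene symbols were matched through the synonyms of the RefSeq table for GRCh38.p14, from which no coordinates were taken; 2478 of 2531 host names matched. Several choices came after the data had been seen: a first look with edgeR at several filters, after which the planned filter was kept, a minimum of 3 tested circRNAs for a list test, the share of reads per list, and the tests of circRNAs sharing a back-splice site. The permutation for circRNAs of the same host was enumerated in full (5040 orders), since only 7 hosts had 2 or more tested circRNAs.

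The edgeR steps were tested on simulated data: 50 data sets with the fitted dispersion, in which 20 circRNAs with a mean of at least 5 were changed. Calls were made for 21.7% of 2-fold, 82.1% of 4-fold and 99.7% of 8-fold changes, and for 0.975% of unchanged circRNAs. These shares covered only circRNAs that passed the filter, with the different folds planted together. The chance of calling a lone change was not simulated. Every circRNA of a data set was drawn with the same common dispersion, so the shares may be lower for circRNAs that vary more between libraries. With a mean of at least 2 and 80 changed circRNAs, the shares called were 4.36%, 34.4% and 75.0%. A 2-fold change planted in the whole adhesion and cytoskeleton list was called by camera in 20 of 20 data sets. The MPA means were raised before filtering, so members below the filter could join the tested set, and circRNAs were drawn independently. The real test of this list had 3 members, so its sensitivity may be lower. Alternatives tried were DESeq2, DESeq2 size factors in edgeR, library totals without TMM, other filters, other thresholds, the replicate number as a block, and each library left out in turn.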

Results

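circRNA sequencing was carried out on Ishikawa human endometrial carcinoma cells, with 3 libraries from MPA-treated cells and 3 from untreated control cells. The 6 libraries held 26060 back-splice junction reads in 4814 circRNAs. Control libraries 1 to 3 held 4316, 3740 and 3743 reads, and MPA libraries 1 to 3 held 4468, 4339 and 5454. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

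Most circRNAs of these cells were exonic (4303 of 4814), with a median predicted length of 551 bases. The table also listed 415 sense-overlapping, 81 intronic, 10 intergenic and 5 antisense circRNAs. A circBase identifier was given for 3799 of them. The circRNAs came from 2531 host genes, of which 1515 had 1 circRNA and 159 had 5 or more. Counts were low: the median circRNA had 3 reads over the 6 libraries, 48.7% were read in 1 library only, and 260 were read in all 6 libraries and held 30.4% of the reads.

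The most abundant circRNA was hsa_circ_0000284 of HIPK3, which encodes a homeodomain-interacting protein kinase (chromosome 11, 33307959 to 33309057, exonic, 1099 bases). It had 26 ± 9 reads in control and 29.7 ± 4.93 reads in MPA libraries (SD, n = 3 each). The next were hsa_circ_0007292 of ATP5C1, the gamma subunit of mitochondrial ATP synthase (chromosome 10, 7839010 to 7844817), hsa_circ_0002805 of the zinc finger gene ZBTB46 (chromosome 20, 62407031 to 62422143), hsa_circ_0001017 of the nuclear export receptor XPO1 (chromosome 2, 61749746 to 61761038) and hsa_circ_0000745 of SPECC1 (chromosome 17, 20107646 to 20109225). ATP5C1 had 23 ± 4.58 reads in control against 21.3 ± 4.93 in MPA libraries, and ZBTB46 17 ± 5.57 against 23.3 ± 4.93. XPO1 had 20.3 ± 4.04 against 18.7 ± 5.51, and SPECC1 14.7 ± 7.57 against 23.3 ± 4.04 (SD, n = 3 each). After scaling to the circRNA totals, the log2 fold changes of these 5 ran from -0.35 to 0.45 and none passed the test (edgeR, smallest adjusted p = 0.936).

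The comparison of MPA-treated with untreated cells asked which circRNAs differed with the treatment. The circRNA with the smallest p was hsa_circ_0000711 of NFATC3, a transcription factor of the calcineurin-regulated NFAT family (chromosome 16, 68155890 to 68160513, exonic, 1298 bases). It had 2, 7 and 3 reads in the control libraries and 13, 14 and 10 in the MPA libraries, a log2 fold change of 1.40 (SE 0.493, n = 3 each) that did not pass the threshold (edgeR, adjusted p = 0.442). Without control library 2 its log2 fold change was 2.14 (edgeR adjusted p = 0.0564); with each other library left out it ran from 1.10 to 1.59 (edgeR adjusted p from 0.256 to 0.937). On the lower side, hsa_circ_0061259 of BAGE3 (chromosome 21, 11038728 to 11058323) had 17, 27 and 16 against 11, 15 and 14 reads, a log2 fold change of -0.83 (SE 0.406, edgeR adjusted p = 0.936). Without control library 2 the BAGE3 value was -0.48. BAGE3 belongs to a family of near-identical copies, so the origin of these reads is uncertain.

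Of 91 circRNAs tested with edgeR, which held 18.9% of the reads, 0 passed an FDR of 0.05, 0 higher and 0 lower with MPA. At an unadjusted p under 0.05 there were 2, 1 higher and 1 lower, where 4.55 are expected by chance. DESeq2 gave 0 past the threshold and 1 at an unadjusted p under 0.05. Point estimates were above 0 for 48 circRNAs and below 0 for 43. The 95% intervals, which are not adjusted for the number of tests, excluded a 4-fold change for 82 of the 91 circRNAs and a 2-fold change for 8. A 2-fold change therefore could not be ruled out for most of them. Without control library 2, 1 circRNA passed: hsa_circ_0000419 of RAB3IP, a regulator of Rab3 and Rab8 vesicle transport, at 1, 14 and 0 reads in control and 16, 9 and 7 in MPA libraries (log2 fold change 4.25, edgeR adjusted p = 0.0314 without that library, against 0.86 and adjusted p = 0.936 with all 6).

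**Figure D1:**
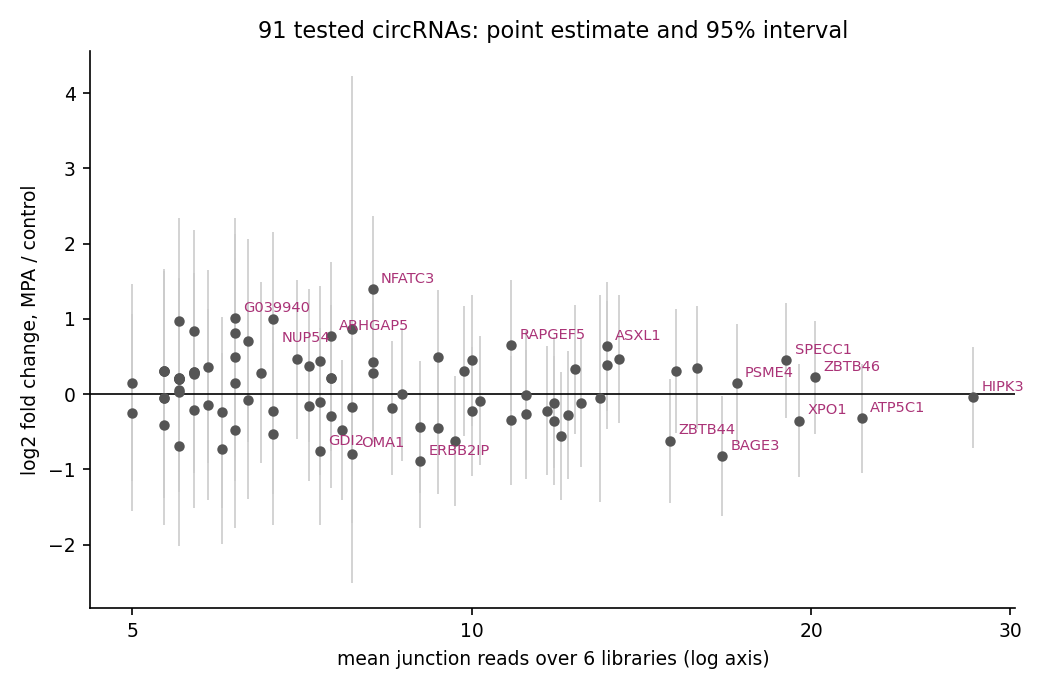
Log2 fold change (MPA over control) of each of the 91 tested circRNAs against its mean junction reads over the 6 libraries on a log axis; points are edgeR estimates and lines are 95% intervals. NFATC3 lies highest at 1.40, and the most abundant, HIPK3, lies at -0.04.

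The other circRNAs with the smallest p among those with higher point estimates came from NUP54, a nuclear pore protein, ARHGAP5, the unnamed locus G039940 and RAPGEF5, an exchange factor for Rap GTPases. hsa_circ_0070039 of NUP54 (chromosome 4, 77055328 to 77065626) had 4 ± 2 reads in control and 9.33 ± 4.04 in MPA libraries. The values were 5 ± 1.73 against 10 ± 1.73 for hsa_circ_0031584 of ARHGAP5 (chromosome 14, 32559708 to 32586493). They were 3.67 ± 1.15 against 8.67 ± 5.03 for hsa_circ_0109327 of G039940 (chromosome 19, 24014399 to 24016323), and 7.67 ± 2.08 against 14 ± 3 for hsa_circ_0133954 of RAPGEF5 (chromosome 7, 22347958 to 22357656; SD, n = 3 each). Among those with lower point estimates were ERBB2IP, a scaffold protein that binds ERBB2, the mitochondrial protease OMA1, the Rab regulator GDI2 and the zinc finger gene ZBTB44. hsa_circ_0001492 of ERBB2IP (chromosome 5, 65284463 to 65290692) had 11 ± 2.65 reads in control and 7 ± 1 in MPA libraries, and hsa_circ_0002316 of OMA1 (chromosome 1, 58971732 to 59004982) had 9.33 ± 1.15 against 6.33 ± 1.53. hsa_circ_0017586 of GDI2 (chromosome 10, 5815805 to 5842668) had 8.67 ± 2.52 against 6 ± 1, and hsa_circ_0002484 of ZBTB44 (chromosome 11, 130130751 to 130131824) had 17 ± 9.64 against 13 ± 1 (SD, n = 3 each). These 8 each had an edgeR adjusted p of 0.936. For ZBTB44 the lower estimate rested on control library 1, without which its log2 fold change moved from -0.62 to -0.02.

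**Figure D2:**
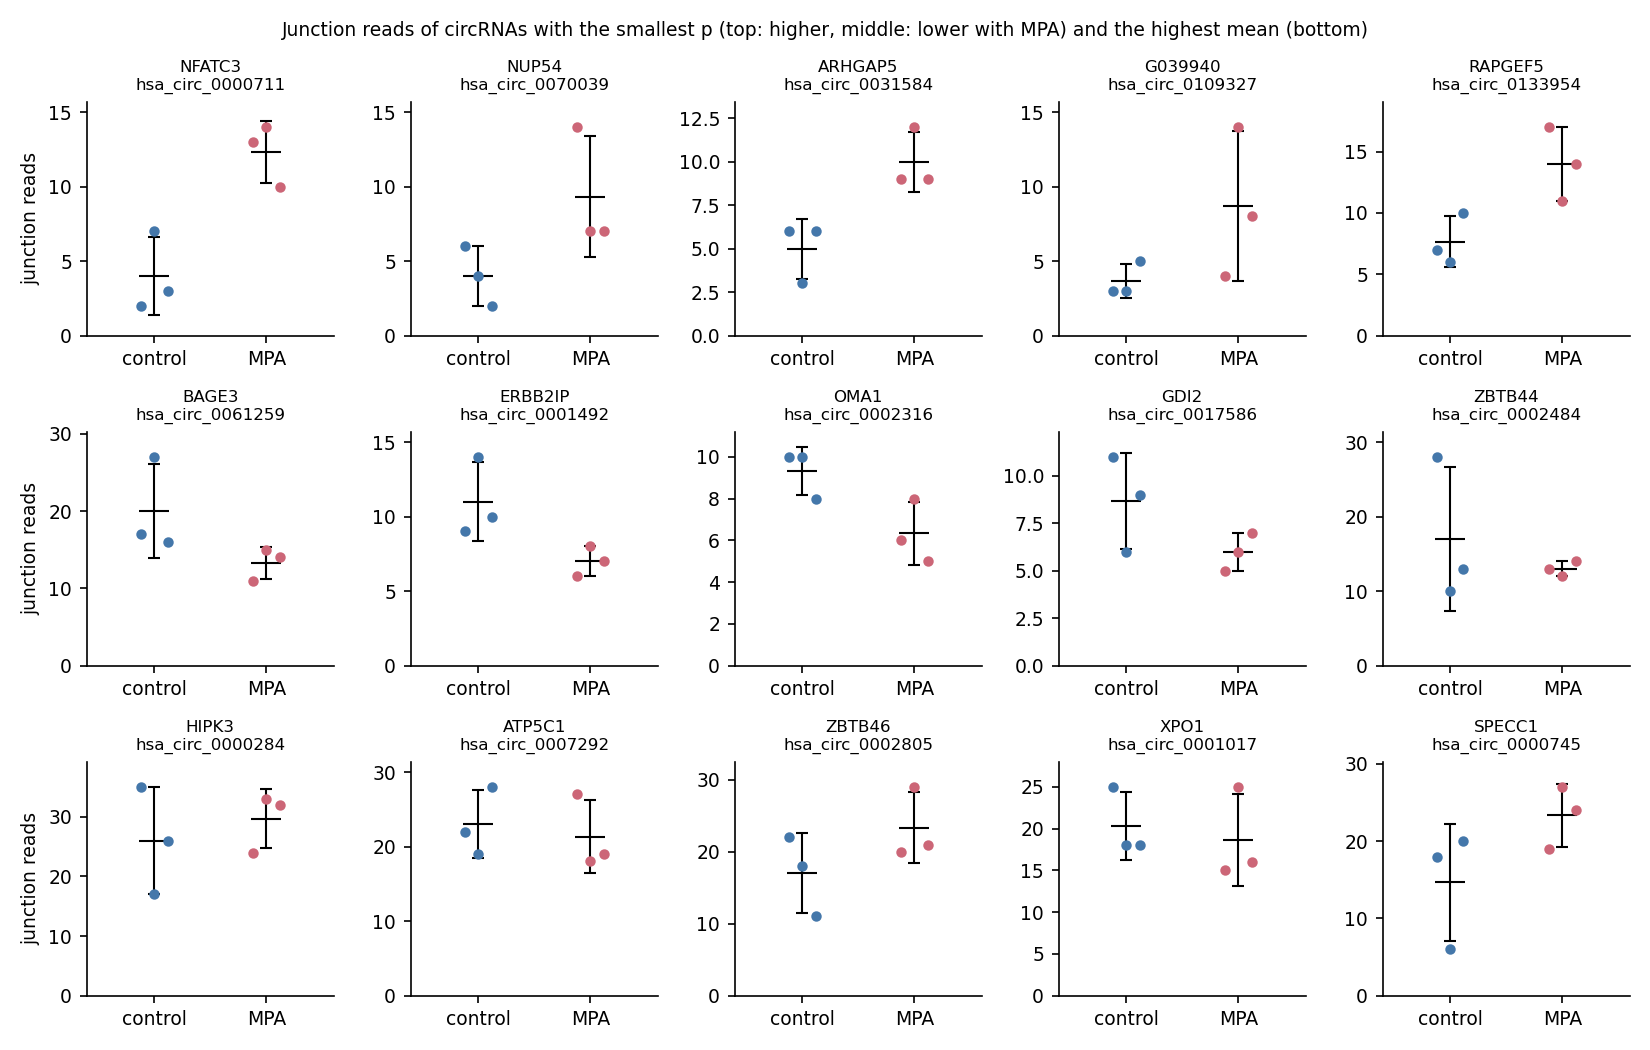
Junction reads per library of the 5 circRNAs with the smallest p and higher estimates (top), the 5 with the smallest p and lower estimates (middle) and the 5 with the highest mean (bottom); points are libraries, and bars are the mean ± SD of 3. For NFATC3 each MPA library, at 10 to 14 reads, lies above each control library, at 2 to 7.

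circRNAs fixed in advance by circBase identifier were read at widely different depths. hsa_circ_0000118 of MAN1A2, a mannosidase of N-glycan processing (chromosome 1, 117944808 to 117963271), had 10.3 ± 3.79 reads in control and 16.7 ± 3.06 in MPA libraries (log2 fold change 0.47, SE 0.432). hsa_circ_0001727 of the zinc finger gene ZKSCAN1 (chromosome 7, 99621042 to 99621930) had 11.3 ± 4.04 against 10.3 ± 5.51 (-0.35, SE 0.436), both with an edgeR adjusted p of 0.936. hsa_circ_0001860 of ZCCHC7 (chromosome 9, 37126309 to 37126939, exonic, 631 bases) had 0, 1 and 0 reads in control and 2, 5 and 2 in MPA libraries. Its share of reads was 7.45 times the control share, with a 95% counting interval of 1.03 to 326, and it lay below the filter; without a filter its edgeR adjusted p was 0.545. hsa_circ_0001821 of PVT1 (chromosome 8, 128902835 to 128903244) had 7, 4 and 2 reads in control and 1, 2 and 3 in MPA libraries (share ratio 0.382, 95% counting interval 0.119 to 1.08). hsa_circ_0000615 of ZNF609 (chromosome 15, 64791492 to 64792365) had 8 and 9 reads, and hsa_circ_0001445 of SMARCA5 (chromosome 4, 144464662 to 144465125) had 2 and 5. hsa_circ_0001756 of HIPK2 (chromosome 7, 139415731 to 139416814) had 4 and 2. hsa_circ_0001313 of CCDC66 (chromosome 3, 56626998 to 56628056) had 0 reads in control and 1, 2 and 3 in MPA libraries, and hsa_circ_0006404 of FOXO3 (chromosome 6, 108984658 to 108986092) had 0 in control and 2, in 1 library, with MPA. The circRNAs known as CDR1as, circFBXW7, circITCH and circMTO1 were also in the fixed set, but were not analysed here.

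Grouped by host gene, chromatin and transcription regulators had 148 circRNAs with 858 reads, of which 4 were tested. hsa_circ_0001136 of the polycomb-associated gene ASXL1 (chromosome 20, 30954187 to 30956926) had 9.33 ± 2.08 reads in control and 17 ± 4.36 in MPA libraries (log2 fold change 0.64, SE 0.436). hsa_circ_0008494 of ARID1A, a subunit of the SWI/SNF remodelling complex (chromosome 1, 27056142 to 27059283), had 4 ± 1.73 against 8.33 ± 3.79 (0.81, SE 0.67). hsa_circ_0000567 of SETD3, whose product methylates actin (chromosome 14, 99924616 to 99932150), had 7.67 ± 1.15 against 7.33 ± 2.08 (-0.29, SE 0.485). The ubiquitin and protein turnover list had 191 circRNAs with 1150 reads, of which 5 were tested. hsa_circ_0001847 of UBAP2, a protein with a ubiquitin-associated domain (chromosome 9, 33953283 to 33963789), had 7 ± 1 against 11.7 ± 5.51 reads. hsa_circ_0001346 of the ubiquitin ligase RNF13 (chromosome 3, 149563798 to 149639014) had 12.3 ± 3.06 against 11.3 ± 2.08, and hsa_circ_0000835 of the ubiquitin ligase MIB1 (chromosome 18, 19345733 to 19359646) had 11.3 ± 0.577 against 11 ± 4.58. In the adhesion and cytoskeleton list, with 108 circRNAs and 3 tested, hsa_circ_0001461 of the cadherin FAT1 (chromosome 4, 187627717 to 187630999) had 10 ± 1 against 10 ± 3.61 reads. hsa_circ_0000231 of ARHGAP12 (chromosome 10, 32197100 to 32199491), had 7 ± 1.73 against 7.33 ± 0.577 (SD, n = 3 each throughout).

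None of these 3 lists passed camera: the adjusted p was 0.780 for chromatin regulators (direction up), 0.780 for ubiquitin and protein turnover (down) and 0.848 for adhesion (up). With an estimated correlation each adjusted p was 0.880. The median log2 fold change of the adhesion list was -0.16 and its mean 0.13, so its median and test differed in sign. In every list with a tested circRNA, 0 circRNAs passed edgeR over all circRNAs and 0 when adjusted over the list alone. The list member with the smallest unadjusted p was ARHGAP5 (edgeR, adjusted p = 0.936 over all circRNAs). No tested list member had an unadjusted edgeR p under 0.05, and DESeq2 also gave 0 over all circRNAs.

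The other 6 lists had too few tested circRNAs for a set test at this filter. With a mean of at least 2, 6 lists could be tested and 0 passed camera: the adjusted p was 0.784 for the cell cycle (12 tested, up), 0.784 for RNA processing (7, down), 0.564 for TGF-beta and Wnt signalling (6, down), 0.448 for chromatin regulators (10, up), 0.448 for ubiquitin and protein turnover (14, down) and 0.784 for adhesion (13, down). At the planned filter, RNA processing and splicing had 82 circRNAs and 2 tested: hsa_circ_0000213 of UPF2, a factor of nonsense-mediated decay (chromosome 10, 12039671 to 12056183), at 4.33 ± 4.04 reads in control and 6.33 ± 3.06 in MPA libraries, and hsa_circ_0000523 of the RNA methyltransferase METTL3 (chromosome 14, 21971316 to 21972024), at 5 in each control library and 5.67 ± 0.577 in MPA libraries. PI3K, AKT and mTOR signalling had 27 circRNAs and 1 tested, hsa_circ_0012300 of the kinase regulatory subunit gene PIK3R3 (chromosome 1, 46521467 to 46546422; 4.33 ± 2.08 against 5.67 ± 2.52). TGF-beta, SMAD and Wnt signalling had 37 and 1 tested, hsa_circ_0001522 of the casein kinase gene CSNK1G3 (chromosome 5, 122881111 to 122893258; 9.67 ± 1.15 against 8.33 ± 3.06; SD, n = 3 each). Cell cycle and DNA replication had 114 circRNAs, with 0 tested. Progestin and decidual response had 10 circRNAs of 7 host genes with 51 reads and 0 tested; chosen after the values were seen, hsa_circ_0001599 of FKBP5, a co-chaperone of steroid receptors (chromosome 6, 35586873 to 35610620), had 7 reads in control and 4 in MPA libraries, and hsa_circ_0001165 of the nuclear receptor coactivator NCOA3 (chromosome 20, 46252655 to 46262380) had 3 and 7. Markers of other cell types had 1 circRNA, of FBN1, with 3 reads over all libraries.

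As a share of all junction reads, a measure added after the data were seen, progestin and decidual host genes took 0.172% ± 0.0633 in control and 0.219% ± 0.03 in MPA libraries. The shares were 2.04% ± 0.308 against 2.20% ± 0.41 for the cell cycle, 3.11% ± 0.312 against 3.44% ± 0.188 for chromatin regulators and 1.46% ± 0.194 against 1.75% ± 0.2 for RNA processing. They were 0.407% ± 0.0177 against 0.483% ± 0.112 for PI3K signalling, 0.984% ± 0.0546 against 0.939% ± 0.145 for TGF-beta and Wnt signalling, and 2.42% ± 0.309 against 2.62% ± 0.274 for adhesion. They were 4.58% ± 0.267 against 4.25% ± 0.966 for ubiquitin and protein turnover, and 0.00891% ± 0.0154 against 0.0154% ± 0.0266 for markers of other cell types (SD, n = 3 each). No list separated the groups, and over the 9 lists the smallest exact permutation p was 0.3 (adjusted p = 0.72).

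**Figure D3:**
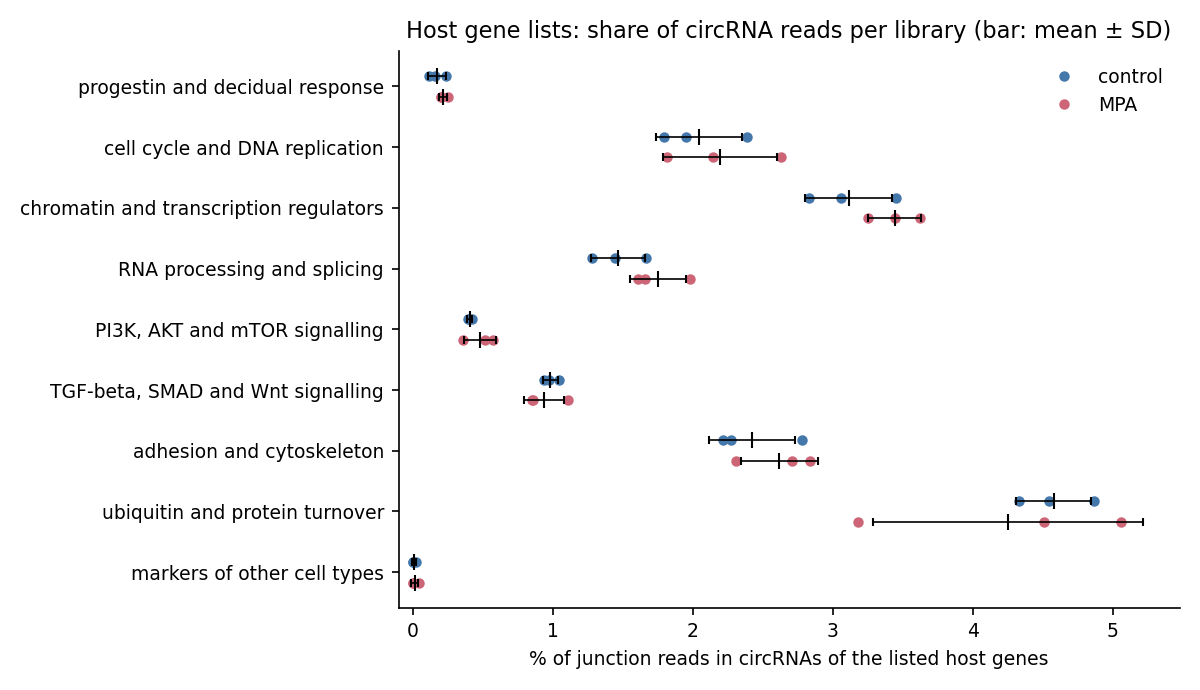
Percent of each library's junction reads in circRNAs of the 9 host gene lists, for control and MPA libraries; points are libraries, and bars are the mean ± SD of 3. The groups overlap in every list, for example at 3.11% and 3.44% for chromatin regulators.

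With reads summed per host gene, the smallest p was found for USP34, a deubiquitinating enzyme, with 2.33 ± 1.15 reads in control and 9.33 ± 5.86 in MPA libraries over 11 circRNAs (log2 fold change 1.76, SE 0.745). ZMYM2, a zinc finger transcription regulator, had 3.67 ± 2.08 against 11.3 ± 4.04 (1.41, SE 0.6), and PPHLN1, periphilin, 3.67 ± 1.53 against 9.67 ± 3.79 (1.17, SE 0.611). STX6, a syntaxin of Golgi transport, had 8.33 ± 5.86 against 3.67 ± 2.89 (-1.40, SE 0.643), and ERBB2IP 18 ± 1 against 12.7 ± 3.21 (-0.73, SE 0.373; SD, n = 3 each). The USP34 value was 1.22 without MPA library 3, and ran from 1.43 to 2.00 with each other library left out. The STX6 value was -0.74 without control library 1 and -2.18 without MPA library 3. All 5 had an edgeR adjusted p of 0.946, and 0 of 180 host genes passed, with 3 at an unadjusted p under 0.05 where 9 are expected by chance. DESeq2 gave 0 past the threshold and 0 at an unadjusted p under 0.05. Without control library 2, 1 host gene passed, RAB3IP (log2 fold change 4.33, edgeR adjusted p = 0.00839, against 0.77 and adjusted p = 0.946 with all 6). Most RAB3IP reads were those of hsa_circ_0000419, so this repeats the result for that circRNA. In 7 hosts with 2 or more tested circRNAs, the log2 fold changes of the 2 most abundant were in the same direction in 3. Only DNAH14 had a further tested circRNA, hsa_circ_0016600 at -0.69, which was not used. Across the 7 hosts, which are not independent replicates, Pearson's r was 0.193 (exact permutation p = 0.665) and Spearman's rank correlation 0.179 (exact permutation p = 0.713). Without the 2 hosts farthest from the median, r was 0.893, so this value depended on which hosts were included.

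At the level of whole libraries, MPA libraries held 4754 ± 610 junction reads and control libraries 3933 ± 332 (SD, n = 3 each), a ratio of 1.21, with every MPA library above every control library (exact permutation p = 0.1, the smallest the design allows). The number of circRNAs with a read was 1831 ± 200 with MPA and 1654 ± 111 in control (exact permutation p = 0.3). Thinned to the smallest total, it was 1682 ± 104 against 1624 ± 59.4 (exact permutation p = 0.6). Sense-overlapping circRNAs took 6.03% ± 0.269 of the reads with MPA and 5.26% ± 0.311 in control, and intronic circRNAs 1.18% ± 0.197 against 1.57% ± 0.147; in both classes the groups did not overlap (exact permutation p = 0.1, adjusted p = 0.25 over 5 classes). Exonic circRNAs took 92.6% ± 0.517 against 93.0% ± 0.325 (exact p = 0.3), intergenic 0.0958% ± 0.0626 against 0.0642% ± 0.0701 (exact p = 0.6) and antisense 0.0782% ± 0.0698 against 0.119% ± 0.0401 (exact p = 0.4). The 10 most abundant circRNAs took 4.22% ± 0.603 against 4.51% ± 0.593 (exact permutation p = 0.8). Without MPA library 3 the difference in reads was 470.5 in place of 821 and that in detected circRNAs 66.7 in place of 177. Among circRNAs with a mean of at least 5, in all libraries, the difference in the sense-overlapping share was 0.276 in place of 0.768 percentage points. At that filter the class held only the circRNAs of ZNF124 and CCNH, and shares were of the reads of tested circRNAs. These values therefore describe different sets.

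**Figure D4:**
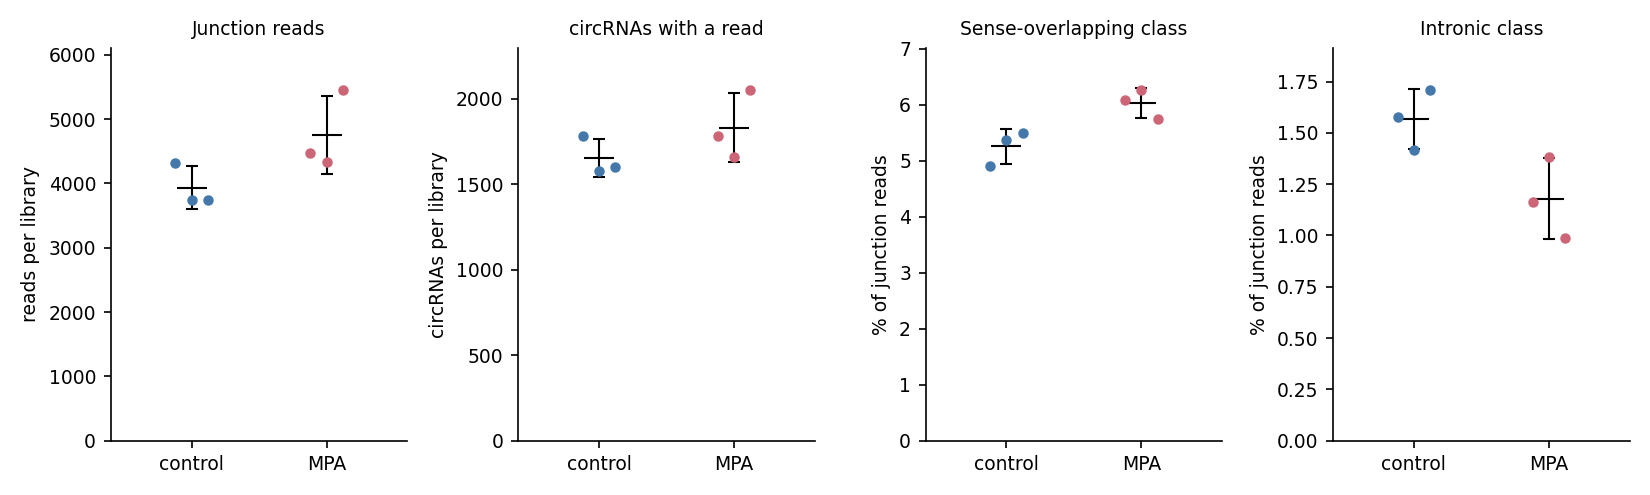
Junction reads, circRNAs with a read, and percent of junction reads in the sense-overlapping and intronic classes, for control and MPA libraries; points are libraries, and bars are the mean ± SD of 3. Reads lie between 3740 and 4316 in control libraries and between 4339 and 5454 in MPA libraries.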

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

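The tests of shared back-splice sites and of read shares per list, with their alternatives, were chosen after the data had been seen; the other alternatives were planned. The counts of 0 changed circRNAs and 0 changed host genes (edgeR; 2 and 3 at an unadjusted p under 0.05) stayed at 0 with DESeq2, DESeq2 size factors, library totals alone, a mean of at least 2 or 10, no filter and an FDR of 0.10. At an unadjusted p under 0.05 with a fold of at least 2 there were 1 circRNA, 1 of them higher, and 3 host genes, by the looser rule itself. Leaving out each library gave 0 to 1 circRNAs, 0 to 1 higher, 0 to 1 host genes and 0 to 2 shared sites (NFATC3 and PAK2). The nonzero values came without control replicate 2. That library held 14 of the 15 control reads of hsa_circ_0000419, which also held most reads of its host gene RAB3IP. The circRNA call and the host gene call are thus not separate results. Why that library differed was not tested. With a mean of at least 2, camera's direction for adhesion was down (median -0.17). Medians ran from -0.22 to -0.0114 (adhesion) and -0.43 to 0.10 (ubiquitin) with libraries left out. Log2 fold changes near 0 changed sign: HIPK3 was 0.0262 with a mean of at least 2 and 0.0312 without a filter, and METTL3 0.0132 and 0.0233. With libraries left out, the ranges were -0.22 to 0.27 (HIPK3), -0.15 to 0.49 (PIK3R3), -0.15 to 0.0607 (METTL3), -0.0718 to 0.48 (ZBTB46), -0.0906 to 1.46 (UPF2), -0.63 to 0.0550 (MIB1) and -0.89 to 0.0112 (ZKSCAN1). Limited to a mean of at least 5, where fewer circRNAs count, the differences were 1 detected circRNA, 149 reads, 0.276 points (sense overlapping) and -1.50 points (top 10). Same-numbered libraries deviated together with correlations of -0.0688, 0.165 and 0.329. Control and MPA libraries with different numbers had correlations from -0.288 to 0.107. The values for numbers 2 and 3 were thus the highest and that for number 1 was not, so pairing by number stays open. With the replicate block, 0 circRNAs, 0 host genes, 0 lists and 0 sites passed. The pseudocount alternative was not run, since it applied to normalized values. List tests with fewer than 3 tested circRNAs, and intronic, intergenic and antisense shares at a mean of at least 5, gave no value. At this depth 98.1% of circRNAs lay below the filter.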

Other observations

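The tests of shared back-splice sites, of circRNAs read in 1 group only, of overlap between libraries, and of where and in which library the extra reads lay were chosen after the result or the counts behind it had been seen; circRNAs named here were also chosen after their values were seen. Several host genes gave families of circRNAs. UTRN, which encodes the cytoskeletal protein utrophin, had 17 circRNAs with 17.7 ± 3.51 reads in control and 17.3 ± 2.08 in MPA libraries, SMARCC1, a SWI/SNF subunit, had 16 with 8.67 ± 3.51 against 16.7 ± 2.08, and XPO1 had 15 with 37.3 ± 12.1 against 36.7 ± 14.2 (SD, n = 3 each). After scaling, the log2 fold change of SMARCC1 was 0.72 (SE 0.424) and did not pass the threshold (edgeR, adjusted p = 0.946). HIPK3 gave 167 reads from 1 circRNA, while DLG1, a scaffold of cell polarity, gave 151 from 12. The BAGE family on chromosome 21 held 10 circRNAs ending at 11058323, 4 named BAGE3, 4 named BAGE2 and 2 named BAGE. Of these, hsa_circ_0061259 had 60 reads in control and 40 with MPA, and hsa_circ_0061261 had 19 and 30; the copies are near-identical, so their separate counts are uncertain.

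A few circRNAs below the filter had uneven reads. hsa_circ_0000943 of ARHGAP35, a repressor of glucocorticoid receptor transcription (chromosome 19, 47421745 to 47440665, sense overlapping), had 2, 0 and 1 reads in control and 5, 12 and 6 in MPA libraries. hsa_circ_0000847 of SMAD2, a transducer of TGF-beta signals (chromosome 18, 45391430 to 45423180), had 7, 5 and 3 reads against 0, 3 and 1. With a mean of at least 2, 0 of 382 circRNAs passed edgeR, with 12 at an unadjusted p under 0.05 where 19.1 are expected by chance; the smallest adjusted p was 0.863, for ARHGAP35 (DESeq2 gave 0 at the planned filter). From the mitochondrial genome, a circRNA listed under OK/SW-cl.16 at 8928 to 9089 had 4 and 14 reads. The antisense circRNA of GABRQ at 151804336 to 151808254 on chromosome X had 7 and 6 reads; whether strand was kept in the libraries is not given in the sources used here.

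MPA libraries held more junction reads than control libraries. Of the extra reads, 97.4% lay outside the 10 most abundant circRNAs (96.3 to 99.5% with each library left out). These 10 held only 4.51% of the reads in control and 4.22% in MPA libraries. An even rise in all circRNAs would therefore also leave most extra reads outside them. The extra reads did not come from 1 library alone. Without MPA library 3 the difference was still 470.5 reads, above the pooled SD of 276. Deeper sequencing of the MPA libraries cannot be told apart from a higher circRNA content, because total depth was not used here. After thinning to the smallest total the groups differed by 58.2 detected circRNAs (pooled SD 84.6), which does not decide between them, since an even rise in circRNAs would look alike. Both may contribute, and the treatment itself stays open.

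circRNAs that share a back-splice site offer a comparison within a gene. At the NFATC3 site, hsa_circ_0000711 had 12 reads in control and 37 with MPA, while hsa_circ_0005615 (68155890 to 68157024) had 5, 1 and 9 against 1, 5 and 2 (edgeR diffSpliceDGE, adjusted p = 0.183 over 46 sites, so chance among the sites tested stays open). A change in transcription of NFATC3, which would move both alike, cannot be told apart from a shift between them, since the groups overlap for hsa_circ_0005615 and the site was looked at because hsa_circ_0000711 had the smallest p. Without control library 2 the adjusted p was 0.0476, and with other libraries left out it ran up to 0.749. Of the 46 sites 0 passed (2 without control library 2), but 8 had an unadjusted p under 0.05 where 2.3 are expected, among them MECOM, NEIL3 and PAK2 (adjusted p = 0.131 each). This count depended on single libraries: it was 4 without control library 1 or MPA library 3, 5 without control library 2, control library 3 or MPA library 1, and 6 without MPA library 2. With a mean of at least 1 it was 15 of 167 sites, where 8.35 are expected. With all libraries, 1 of the 10 splits of the 6 libraries gave as many, the real one, and the highest other was 4. A treatment-linked shift in back-splice partner choice is therefore no more than a hypothesis, which deeper libraries could test.

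Which circRNAs were read did not set the groups apart. A read in every library of 1 group and none of the other was found for 58 circRNAs, against up to 71 in other splits, and 7 of the 10 splits gave at least as many. The overlap of detected circRNAs (Jaccard) was 28.1% within and 28.3% between groups, a difference of -0.183 percentage points, where other splits had a median of -0.0515 with an SD of 0.276 and reached 0.402; an effect of the treatment on which circRNAs are read cannot be told apart from none at this spread. For the counts past the threshold, whose real values were 0, every split had to give at least as many, so the 10 of 10 splits decide nothing for changed, higher and lower circRNAs, host genes, lists and shared sites; the highest other values were 1, except 0 for lists (edgeR; DESeq2 also gave 0 changed circRNAs, with 2 and 1 circRNAs at an unadjusted p under 0.05 in edgeR and DESeq2). At that unadjusted p, 9 of the 10 splits gave at least 2 circRNAs, and the highest other was 7. With 10 splits the share cannot fall under 0.05.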
